A study of Mus musculus with 8 samples.

How the data were processed

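RNA was sequenced from naive CD4+ T cells that had been purified from the spleen of male mice with a naive T cell isolation kit, per the labels' protocols. The 8 libraries carry the titles E1KO or E1WT, 4 of each, and were prepared with a kit for Illumina sequencing and read as paired ends. TopHat2 2.1.0, HTSeq 0.9.1 and the mouse build mm10 are named, per the submitters' processing notes. The gene annotation, the strand setting and the filters are not given in the sources used here.

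The deposited files hold raw read counts, 1 whole number per gene symbol and library, with 24421 symbols in each. Another 5 rows per file hold reads that the authors' counting gave to no gene, and these were left out of library sizes and tests. They made up 28.2% to 37.0% of all counts in a file, and the rows for low alignment quality and unaligned reads are listed at 0 in every library. Reads aligned to several places have a row of their own, so genes with near-identical copies are counted in part.

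Libraries were grouped by title. In all 8 samples the genotype characteristic states the opposite of the title, and the titles were the label fixed for grouping. Every fold is E1KO-titled over E1WT-titled. Nothing beyond the word for 4 replicates in the design text says that the libraries came from separate animals, so p-values measure the spread between these libraries, which may be technical. The libraries of a title differed beyond sampling noise in every pair, with a chi-square per degree of freedom of 4.20 to 64.4, and each was counted as 1 replicate.

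Genes were tested with edgeR 4.0.16 in R 4.3.3, using TMM scaling, its default expression filter (count minimum 10, total count minimum 15) and the quasi-likelihood test, with Benjamini-Hochberg adjustment at 0.05. The filter left 13333 genes. CPM values are scaled by TMM, and log2 CPM values used a prior count of 2. Errors of log2 folds are standard errors derived from the edgeR F statistic, and errors of CPM are standard deviations over 4 libraries. Measures of single libraries were compared with two-sided exact permutation tests, where 4 against 4 cannot give a p below 0.0286.

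A total of 26 gene lists and 12 marker lists of other cell types and sex were fixed, like the grouping, before the data were examined. Lists with at least 5 tested members were tested with camera in limma 3.58.1 at a preset correlation of 0.01, and again with an estimated correlation. The 26 gene lists and the 9 tested marker lists were adjusted as separate families. Genes named in the text are the PCBP family, the 10 largest rises and 10 largest falls among called genes with a mean log2 CPM of at least 1 and no overlap between the titles (predicted gene models left out), and up to 4 called members of each list with the smallest p, or the 2 with the smallest p where none was called. Genes outside this rule are said to be chosen after their values were seen, and the values of 2 list members are not reported here.

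Gene positions come from GENCODE M21 on GRCm38, the same assembly as mm10. Of the symbols, 23376 matched a gene name, 651 matched through an older symbol and 394 did not match. Figures were drawn with matplotlib.

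The gene test was checked on simulated counts with 13200 genes in the fit, 4 against 4 libraries and the dispersions of the real data. It recovered 20% of genes changed by 1.25-fold, 62.5% at 1.5-fold, 84% at 2-fold and 91.8% at 4-fold, and 2.26% of its calls were unchanged genes. These shares came from 48 to 50 changed genes per fold and 133 calls. The real data gave 3108 calls, so the shares need not carry over to them. Of 40 random lists, 0 were called by camera. The simulated genes were drawn independently of one another. This result therefore does not cover lists whose members move together. Alternatives covered scaling, filters, DESeq2 1.42.0, limma-voom, the replicate number as a block, each library left out in turn and the grouping field. Removal of an exon-length trend, leaving out the E1KO 1 and E1WT 4 libraries together, autosomal genes only and a fold threshold were added after the data were seen. Libraries differed in how log2 CPM, relative to the mean over libraries, followed exon length. Spearman correlations ran from -0.32 (E1KO 3) to 0.22 (E1KO 1) and from -0.26 (E1WT 2) to 0.32 (E1WT 4). They did not separate the titles (two-sided exact permutation p = 0.43).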

Results

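Naive CD4+ T cells from the spleens of C57BL/6 mice were profiled by RNA sequencing in wild-type animals and in animals with a floxed Pcbp1 gene and a Cd4-driven Cre recombinase. PCBP1, also called hnRNP E1, is an RNA-binding protein with KH domains that binds C-rich RNA, and Cd4-Cre deletes floxed genes in T cells during thymic development. The comparison asks how the naive CD4+ transcriptome differs without PCBP1. There were 4 libraries titled E1KO and 4 titled E1WT, with 28264655 to 36738202 gene counts each. Titles and genotype fields contradict each other in all 8 samples, so libraries are named by title throughout and each direction is that of the titles. The first principal component held 44.7% of the variance and separated the titles (two-sided exact permutation p = 0.0286, the smallest possible).

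Pcbp1 was low in every library titled E1KO and high in every library titled E1WT, which goes with the titles and against the genotype fields. Its level was 39.7 ± 1.57 CPM in E1KO-titled and 224 ± 16.3 CPM in E1WT-titled libraries (SD, n = 4 each), so 17.7% of the E1WT level remained. Single libraries lay at 38.3 to 41.8 CPM and at 203 to 243 CPM. The log2 fold was -2.49 ± 0.07 (SE), with an adjusted p of 2.57e-09 in the edgeR quasi-likelihood test. Pcbp1 is a single-exon gene on the minus strand of chromosome 6, from 86524492 to 86526321 (GRCm38). The antisense gene 1600020E01Rik, at 86526247 to 86582466 on the plus strand, overlaps it by 75 bp and had a log2 fold of -4.20 ± 0.23. It was chosen after its values were seen, and since strand use is not given, reads from the shared stretch cannot be assigned to either gene.

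The related family members did not follow Pcbp1. Pcbp2, the closest paralog, stood at 322 ± 14.6 and 344 ± 21.3 CPM (log2 fold -0.10 ± 0.06, adjusted p = 0.28 in edgeR), and Pcbp3 had a log2 fold of 0.26 ± 0.11 (adjusted p = 0.12). Pcbp4 rose by 0.37 ± 0.09 (adjusted p = 0.013), from a mean of 13.2 to 17.1 CPM. In the list of PCBP and hnRNP genes 5 of 23 tested members rose and 1 fell, and with adjustment over the list alone the counts were also 5 and 1 (camera adjusted p = 0.31). The 1 that fell, Hnrnpr, lost its call with the exon-length trend removed (log2 fold -0.007, edgeR adjusted p = 0.96). Hnrnph2, which rose, lost it without the E1KO 4 library (edgeR adjusted p = 0.057). Genes that lay within 10 Mb of Pcbp1 were called at 19.3% (21 of 109), against 23.4% elsewhere (odds ratio 0.78, two-sided Fisher's exact p = 0.36). Without the E1WT 1 or the E1WT 4 library the odds ratio was 0.485 (exact p = 0.022) or 0.525 (exact p = 0.024).

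Across all genes, 1623 were higher and 1485 lower in E1KO-titled libraries out of 13333 tested, and 388 and 215 of these changed at least 2-fold. All 4 libraries of one title lay above or below all 4 of the other for 26.0% of tested genes, where chance gives 2.86%. The largest rise was that of Xist, the RNA that coats the inactive X chromosome, at 397 ± 30.9 against 1.51 ± 1.09 CPM (SD, n = 4 each). Xist separated the titles in every library, as did the Y-linked genes, so differences between titles cannot be told apart from this signal. Among the next largest rises were Nlrp1b, an inflammasome sensor at chromosome 11, 71153102 to 71230733 (log2 fold 2.95 ± 0.40), and Slfn8, a Schlafen family gene on the same chromosome at 83002158 to 83020810 (2.80 ± 0.18). Pla2g4f, Wisp1, Dscam, Phlda3, Trpm1, Rundc3a and Slc25a21 rose by 1.92 to 2.40. The largest fall was that of Sostdc1, an extracellular antagonist of BMP and Wnt signalling (-4.35 ± 0.33, 0.37 ± 0.21 against 7.63 ± 0.73 CPM). Falls of -2.74 to -2.00 were seen for Tgfbr3l, Fam196b, H2-Q5, Spp1, Pmel, Stfa3, Tmod4 and Cd109, with Pcbp1 among them. H2-Q5, Slfn8 and Nlrp1b have close relatives whose reads can be shared, and Pmel (chromosome 10, plus strand, ending at 128720238) overlaps the end of Dgka (minus strand, starting at 128720134), so these values are uncertain.

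Cell cycle genes rose together. Of 40 tested members 27 rose and 0 fell, and with adjustment over the list alone 32 rose, with a median log2 fold of 0.45 (camera adjusted p = 3.3e-13, and adjusted p = 0.017 with an estimated correlation). Cdc6, which loads the replicative helicase, rose from 7.20 ± 0.34 to 14.5 ± 1.47 CPM (log2 fold 1.01 ± 0.10), and Ccna2, Mcm7 and Rrm1 rose by 0.71 ± 0.09, 0.51 ± 0.05 and 0.50 ± 0.05. Markers of erythroid cells were also higher in the E1KO-titled libraries, with a median log2 fold of 0.96.

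Regulatory T cell genes were mostly higher. In this list 14 of 27 rose and 3 fell (16 and 4 with adjustment over the list alone), the median log2 fold was 0.43, and the list passed camera at an adjusted p of 0.00017 and with an estimated correlation at 0.021. Penk, a proenkephalin gene, rose from 6.90 ± 1.26 to 24.2 ± 2.66 CPM (log2 fold 1.81 ± 0.14), and Il2ra, the alpha chain of the interleukin-2 receptor, rose by 0.59 ± 0.05. Foxp3, the lineage transcription factor, rose by 0.46 ± 0.05 and was named after its value was seen. The members that fell were Izumo1r (-0.68 ± 0.06), the low-expressed Plagl1 (-1.32 ± 0.20) and Gpr83 (-0.38), the last 2 named after their values were seen. Of the 27 members 10 also belong to another list. The NK, monocyte and dendritic markers described further on rose in the same libraries.

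Genes of activated and memory T cells rose in 12 of 34 cases and fell in 2, with 14 and 4 when adjusted over the list alone (camera adjusted p = 0.0039, adjusted p = 0.20 with an estimated correlation). Tnfrsf9, a costimulatory receptor, rose by 0.83 ± 0.06, Lgals3 by 1.04 ± 0.11 and Vim by 0.50 ± 0.05 on the log2 scale. The 2 that fell were Maf (-0.50) and Cxcr6 (-0.56), named after their values were seen. Of the 34 members 13 also belong to another list, and monocyte, dendritic and NK markers rose in the same libraries, with list medians of 0.63, 0.72 and 0.60. The NRF2 and antioxidant genes rose in 6 of 27 cases, Nqo1, Cat, Tkt and Osgin1 among them, with 0 falling and 6 and 0 over the list alone (camera adjusted p = 0.019, adjusted p = 0.12 with an estimated correlation). Translation factors rose in 9 of 36 cases with 0 falling, also 9 and 0 over the list alone, with Eif4ebp1, an inhibitor of eIF4E, at 1.20 ± 0.14 (camera adjusted p = 0.043, adjusted p = 0.22 with an estimated correlation). That call ended with the DESeq2 size factors, the DESeq2 test, the CPM filter, the exon-length trend removed, autosomal genes alone and E1KO 1 and E1WT 4 both left out (adjusted p = 0.053 to 0.089), and without any 1 of the libraries E1KO 1, E1KO 4, E1WT 1, E1WT 2 and E1WT 3, where the adjusted p was 0.062 to 0.079.

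Genes of the T cell receptor complex and its proximal signalling fell. Of 27 tested members 13 fell and 0 rose (16 and 0 with adjustment over the list alone), the median log2 fold was -0.20, and the list passed camera at an adjusted p of 2.3e-06 and with an estimated correlation at 0.017. Zap70, the kinase recruited to the activated receptor, went from 360 ± 4.77 to 254 ± 5.61 CPM (log2 fold -0.51 ± 0.05), and Plcg1 and Cd3g fell by 0.38 ± 0.05 and 0.42 ± 0.06. Cd4 had a log2 fold of -0.27 ± 0.05 and Cd3e one of -0.25 ± 0.12 (adjusted p = 0.0037 and 0.15 in edgeR), both named after their values were seen. In the same libraries dendritic, monocyte, NK and erythroid markers rose, with list medians of 0.60 to 0.96.

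Follicular helper genes fell as well. Of 16 tested members 8 fell and 1 rose (9 and 1 with adjustment over the list alone), the median log2 fold was -0.34, and the list passed camera at an adjusted p of 3.1e-05 and with an estimated correlation at 0.021. Il21, the cytokine of follicular helper cells, went from 7.57 ± 0.34 to 2.12 ± 0.56 CPM (log2 fold -1.83 ± 0.18), Cxcr5, which guides T cells to follicles, fell by 0.67 ± 0.06, and Btla and Cd40lg fell by 0.52 ± 0.06 and 0.58 ± 0.07. Bcl6 had a log2 fold of -0.34 ± 0.06 and the member that rose was Cd200 (0.26), both named after their values were seen. The other-cell markers that rose, with list medians of 0.60 to 0.96, did so in these same libraries.

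The naive and quiescent list was split, with 9 of 26 members lower and 5 higher (12 and 5 with adjustment over the list alone; median -0.14). Dgka, a diacylglycerol kinase that limits receptor signalling, fell by 1.37 ± 0.05, Satb1 by 0.42 ± 0.05 and Tcf7 by 0.37 ± 0.05 on the log2 scale. Igfbp4, Klf2, Dapl1 and Ccr9 were among those that rose, by 0.57 ± 0.05 for Igfbp4, and the latter 3 were named after their values were seen. The list as a whole passed camera (adjusted p = 0.032) but not with an estimated correlation (adjusted p = 0.32) or without the E1WT 4 library (adjusted p = 0.063), without E1KO 1 and E1WT 4 together (0.062) or with the exon-length trend removed (0.081), where the median log2 fold was -0.11, -0.13 and -0.13. Cytoplasmic ribosomal proteins had a median log2 fold of -0.10, and 1 of 74 members, Rpsa, passed (0 over the list alone). The list passed camera at an adjusted p of 0.018, but its members moved together so closely (estimated correlation 0.85) that the adjusted p was 0.77 with that estimate. The call also ended without the E1KO 1, E1KO 2 or E1WT 2 library, at adjusted p values of 0.29, 0.085 and 0.19. The median log2 fold was then -0.039, -0.066 and -0.038. Rpsa lost its call without the E1KO 2 or the E1WT 1 library (edgeR adjusted p = 0.055 and 0.053).

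**Figure D1:**
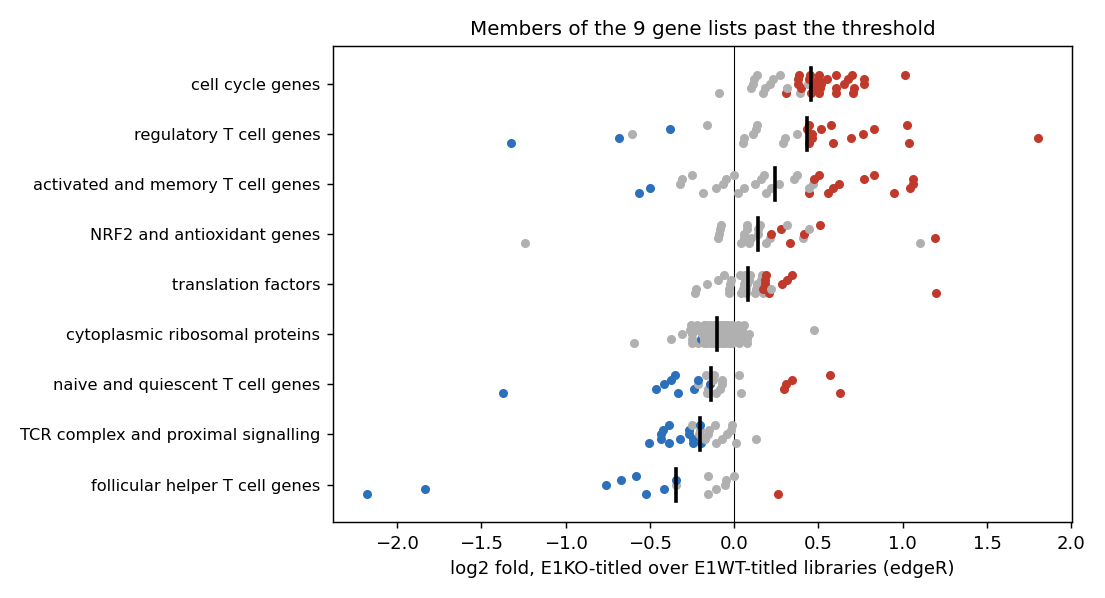
Log2 folds from edgeR (horizontal axis, E1KO-titled over E1WT-titled libraries) of the members of the 9 gene lists that passed camera with the preset correlation. Points are genes, red or blue where they rose or fell past the threshold and grey otherwise, and black bars are list medians, from 0.45 for cell cycle genes to -0.34 for follicular helper genes.

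The other 17 gene lists did not pass camera, with adjusted p values of 0.078 to 0.78. With no filter on low counts the apoptosis, oxidative phosphorylation, iron, and glycolysis and hypoxia lists passed (adjusted p = 0.043 to 0.047). With the default filter and an estimated correlation, their camera adjusted p values were 0.21, 0.77, 0.42 and 0.21. Among the 17 lists, immediate early and receptor-induced genes were split, with 5 of 27 higher and 7 lower (9 and 8 over the list alone), and Egr3 (-0.51 ± 0.06) and Nr4a2 (1.11 ± 0.15) went apart. The type I interferon list had 3 of 40 higher and 8 lower (3 and 8 over the list alone; camera adjusted p = 0.078), with Slfn8 and Oas1a up and Xaf1 down. That list passed, as lower, without the E1KO 3 library (adjusted p = 0.035) and with the exon-length trend removed (adjusted p = 0.012). With an estimated correlation over all 8 libraries its camera adjusted p was 0.23. Lists of p53 targets (8 of 29 higher, 2 lower) and of BCL2 and death receptor family genes (10 of 29 higher, 1 lower) included Bbc3, a pro-apoptotic BH3-only gene, at 1.12 ± 0.12, and Fasl at -1.17 ± 0.11. With adjustment over the list alone these counts were 8 and 2, and 10 and 2. Genes of the unfolded protein and integrated stress response rose in 8 of 31 cases and fell in 3 (9 and 4 over the list alone), led by Asns, asparagine synthetase, which went from 3.58 ± 0.20 to 13.3 ± 1.28 CPM. Iron homeostasis genes rose in 7 of 30 cases and fell in 1 (also 7 and 1 over the list alone), with Steap3, an iron reductase, at 1.51 ± 0.11 and Tfrc, the transferrin receptor, at 0.51 ± 0.06. Erythroid markers rose in the same libraries, with a list median of 0.96, so these rises cannot be assigned to the T cells. Heat shock genes had 3 of 18 higher and 2 lower (4 and 2 over the list alone), the 2 being the near-identical pair Hspa1b (-1.98 ± 0.11) and Hspa1a (-1.78 ± 0.18).

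Of the other lineage lists, Th1 and cytotoxic genes rose in 5 of 24 cases and fell in 4 (6 and 4 over the list alone), with Gzmk at 1.37 ± 0.16 and Eomes at 0.66 ± 0.07. Eomes is also in the NK marker list, of which 6 of 9 members rose in the same libraries. Th2 genes rose in 3 of 8 cases and fell in 0 (3 and 0), namely Il1rl1, Ccr8 and Bhlhe41. Th17 genes rose in 3 of 12 cases and fell in 3 (3 and 3), with Ahr at 0.75 ± 0.09 and Il6st at -0.66 ± 0.11. Coinhibitory receptors rose in 4 of 16 cases and fell in 4 (5 and 4), with Lag3 at -0.76 ± 0.09 and Klrg1 at 1.04 ± 0.20. TGF-beta signalling genes rose in 4 of 29 cases and fell in 3 (4 and 3), with Pmepa1 at 0.74 ± 0.09. Counts in brackets are those adjusted over the list alone.

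In the metabolic and RNA-processing lists, glycolysis and hypoxia genes rose in 5 of 27 cases and fell in 3 (9 and 4 over the list alone), Pdk1 having a log2 fold of -0.55 ± 0.05. Cholesterol biosynthesis genes rose in 3 of 24 cases and fell in 2 (3 and 2). Those that fell, Nsdhl and Mvk, each lost the call without any 1 of the libraries E1KO 1, E1KO 2, E1WT 1 and E1WT 2 (edgeR adjusted p = 0.055 to 0.12), and of those that rose Lss lost it without the E1KO 4 library (0.053) and Mvd without any 1 of the libraries E1KO 3, E1KO 4, E1WT 1, E1WT 3 and E1WT 4 (0.060 to 0.093). Splicing regulators rose in 2 of 35 cases and fell in 5 (2 and 5). Of 52 oxidative phosphorylation genes 1, Cycs, rose and 0 fell, with 0 and 0 over the list alone. Cycs lost its call without the E1KO 3 or the E1KO 4 library (edgeR adjusted p = 0.0502 and 0.063). That list stood at an adjusted p of 0.09 in camera (median log2 fold 0.080) and passed without the E1KO 1, E1KO 2 or E1WT 2 library (adjusted p = 0.0037, 0.043 and 0.0065). Its median was then 0.170, 0.111 and 0.165. With an estimated correlation (0.79) over all 8 libraries, the camera adjusted p was 0.77.

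Markers of other cell types differed between the titles. Dendritic cell markers rose in 9 of 12 cases (median log2 fold 0.72, camera adjusted p = 0.00019), monocyte and macrophage markers in 7 of 14 (0.63, 0.00099), NK cell markers in 6 of 9 (0.60, 0.0026) and erythroid markers in 4 of 6 (0.96, 0.0017), with 10, 9, 6 and 4 when adjusted over each list alone. With an estimated correlation the adjusted p values were 0.038 for dendritic and 0.046 for each of the other three. Summed CPM per library was 1.21, 1.34, 1.44 and 2.56 times the E1WT level for dendritic, monocyte, NK and erythroid markers. Plasma cell markers, not called by camera, stood at 1.35 times, with Jchain alone at 803 against 556 CPM. For each of these sums the two-sided exact p was 0.0286. After Benjamini-Hochberg adjustment over the 12 marker lists it was 0.0571, so none passed. Sums of the remaining cell types ran from 0.856 (CD8 T cells) to 1.20 (gamma-delta T cells) times, with an exact p of at least 0.0571. Lyz2, the lysozyme of myeloid cells, went from 22.3 ± 3.03 to 57.8 ± 5.96 CPM, and Car1, a carbonic anhydrase of the erythroid lineage, from 35.3 ± 6.02 to 103 ± 13.8 CPM. Slc4a1, among the erythroid markers that rose, lost its call without any 1 of the libraries E1KO 1, E1KO 3, E1KO 4, E1WT 1, E1WT 2 and E1WT 4 (edgeR adjusted p = 0.057 to 0.12). The low-expressed C1qb was the 1 monocyte marker that fell (0.023 against 0.462 CPM), and it was named after its value was seen. B cell markers showed 5 of 16 higher and 2 lower (7 and 3 over the list alone; median 0.09, camera adjusted p = 0.56).

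Of the remaining marker lists, the plasma cell list had 1 of 7 higher, Jchain (1 over the list alone, camera adjusted p = 0.13), the neutrophil list 1 of 12 higher and 3 lower (1 and 4, adjusted p = 0.39) and the stromal list 0 of 9 either way in edgeR (0 over the list alone, adjusted p = 0.45). At an unadjusted p under 0.05, 0 of the stromal markers were higher and 2 lower, and DESeq2 called 0 and 0. In the neutrophil list S100a8 and Ltf, both lower, lost the call without any 1 of the libraries E1KO 2, E1KO 3, E1WT 1, E1WT 3 and E1WT 4 (edgeR adjusted p = 0.057 to 0.12), and Mpo, the 1 that rose, lost it without E1KO 1, E1KO 4, E1WT 1 or E1WT 3 (0.072 to 0.098). Sparc and Col3a1 were called lower in edgeR without the E1KO 1 library (adjusted p = 0.0067 and 0.0060) and without E1KO 1 and E1WT 4 together (0.0033 and 0.0044), and limma-voom called Sparc lower (0.041). Lists of CD8 T cell, gamma-delta T cell and platelet markers had fewer than 5 tested members, of which Cd8a fell and Blk and Gp5 rose, 1 in each. Blk lost its call without any 1 of the libraries E1KO 3, E1KO 4, E1WT 1, E1WT 3 and E1WT 4 (edgeR adjusted p = 0.055 to 0.073). The sex list had Xist higher and Kdm5d, Eif2s3y, Ddx3y and Uty lower, each of these 4 by 0.98 to 1.08 on the log2 scale, so its median (-0.996) and mean (0.796) differ in sign. It passed camera as lower (adjusted p = 0.0017) but not with an estimated correlation (adjusted p = 0.11). The share of reads falling in no annotated gene was 16.4% ± 0.92 in E1KO-titled and 20.6% ± 1.39 in E1WT-titled libraries (SD, n = 4 each; two-sided exact p = 0.0286, Benjamini-Hochberg adjusted 0.0786 over 11 library measures). Reads aligned to several places (11.6% against 12.9%) and the TMM factor (1.02 against 0.979) were also separated by title, with the same exact and adjusted p.

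**Figure D2:**
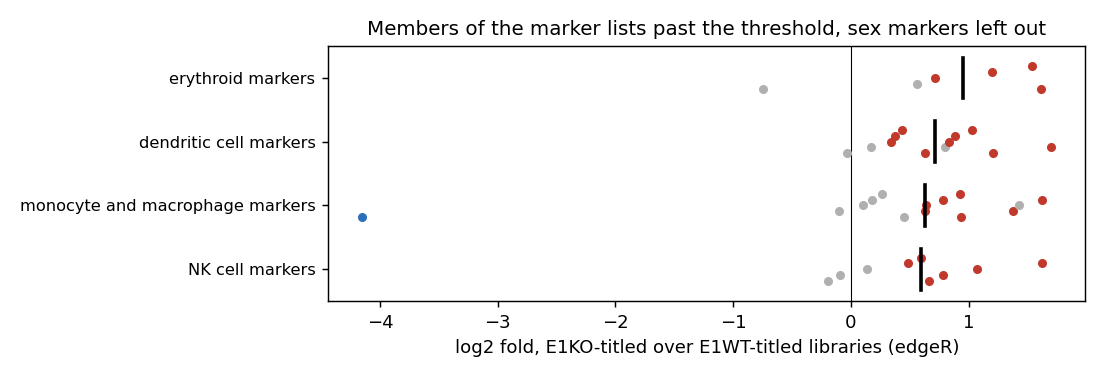
Log2 folds (horizontal axis, E1KO-titled over E1WT-titled libraries) of the members of the erythroid, dendritic, monocyte and NK marker lists. Points are genes, coloured where past the threshold and grey otherwise, and black bars are list medians of 0.60 to 0.96; C1qb is the blue point far to the left.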

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

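The tests of the Xist and Y-linked pattern and of the marker pattern were chosen after their results were seen, and those of the MHC class I pattern and of other splits were written before. The MHC pattern itself was found by looking through the genes, and the rule that a bound must be passed by more than 1 standard error was added after its value was seen.

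Xist stood at 365 to 426 CPM in the E1KO-titled libraries and at 0.55 to 2.89 CPM in the E1WT-titled ones, and the 4 Y-linked genes together were at 47.6% to 52.7% of the mean E1WT level in each E1KO-titled library. Libraries made from female mice alone are argued against by the Y-linked genes, which kept 49.3% of the E1WT level, where under 5% would be needed. Silencing of the X chromosome by Xist in male cells is argued against because the median log2 fold of X-linked genes lay 0.0235 above that of autosomal genes. Female cells mixed into these libraries are a candidate explanation, since the Y-linked genes fell by nearly 1 factor (range of log2 folds 0.10), but genes that escape X inactivation did not rise as a group, with a median log2 fold of 0.0036 over 7 genes, of which 1, Eif2s3x (0.34 ± 0.10), passed, while Pbdc1 and Kdm6a stood at 0.33 and 0.14 and Kdm5c, Ddx3x, 5530601H04Rik and Utp14a at 0.00, -0.01, -0.05 and -0.10. The labels give male mice only and no E1KO-titled library lacks the signal, so the source stays open. If cells of both sexes were mixed, each such library held cells of more than 1 mouse. Whether the libraries then shared a pool is not given, so their spread may not be that between animals. Every difference between the titles goes with this signal and cannot be told apart from it.

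The erythroid, monocyte, dendritic and NK markers were higher in E1KO-titled libraries, and B cell markers were not called as a list. A lower share of T cells with an unchanged mix of the other cells would raise every other cell type alike. The 8 tested marker lists of other cell types did not rise alike (permutation p = 0.00015 of the Kruskal-Wallis statistic). That statistic was taken across 77 genes held by 1 of these lists, which are not independent replicates. The lists were already known to differ when this test was chosen. Some plasma cell markers, Irf4 and Prdm1 among them, also belong to the activated and memory T cell list. The test thus does not decide this explanation. Median log2 folds ran from -0.49 for stromal markers, of which 0 of 9 were called, and -0.03 for neutrophil markers to 0.96 for erythroid ones. A lower share of T cells with a changed mix of other cells is not addressed by this test and also stays open. More erythroid progenitors could raise the erythroid markers: Kit, Gata2, Tal1, Epor, Gfi1b, Tfr2 and Ermap, outside the fixed list, had a median log2 fold of 1.26, and all 7 passed. This stays open, since 10 globin genes are listed at 0 in every library and the most abundant red cell transcripts cannot be read, and a change of the T cells themselves was not tested. Of the tested markers 0 of 6 erythroid, 2 of 14 monocyte, 4 of 12 dendritic and 4 of 9 NK ones also belong to another list, and the isolation kit is meant to remove such cells.

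MHC class I genes on chromosome 17 were lower in E1KO-titled libraries: 10 of 12 tested fell and 0 rose, with a median log2 fold of -0.90 and H2-K1 at -1.09 ± 0.08. In a scan of 1437 windows of 2 Mb for genes with a log2 fold of at least 1 either way, which leaves out the smaller class I falls, the window from 34000001 to 36000000 on chromosome 17 ranked 2 (8 of 81 genes, unadjusted Fisher's exact p = 0.0017), and no window passed after adjustment (adjusted p 1). Another MHC haplotype that is counted less may account for it and cannot be told apart from other causes. Class I pathway genes outside the MHC had a median log2 fold of -0.175, with single genes from -0.74 (B2m) to 0.02 (Canx). The added margin of 0.06 is the standard error from the 2 middle genes alone, Psmb10 and Erap1. It does not cover the spread over the 6 genes. With this margin the value reached across the bound of -0.2, and without it the value lies on the side of that explanation. A lower class I programme is also open, since B2m (-0.74 ± 0.11) and Nlrc5 (-0.31 ± 0.06), which lie outside the MHC, had a median log2 fold of -0.53, but not every pathway gene fell: Psmb10 (-0.09), Pdia3 (-0.05) and Canx (0.02) outside the MHC and Tap2 (-0.13), Tapbp (-0.13) and Psmb8 (-0.15) inside it were not called, while Erap1 (-0.26), Tap1 (-0.59) and Psmb9 (-0.63) fell.

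Single libraries stood apart from the other 3 of their title for 14 of 290 groups of values tested, or 4.83%, and about 1 in 20 is expected by chance. Among E1KO-titled libraries these were Phlda3 at 7.92 CPM and Steap3 at 16.5 CPM in E1KO 3, Sostdc1 at 0.061 CPM, Blk at 14.4 CPM and Itgax at 10.7 CPM in E1KO 2, Tfrc at 55.3 CPM in E1KO 4 and Nqo1 at 1.57 CPM in E1KO 1. Among E1WT-titled libraries these were Fam196b at 6.41 CPM and Xcr1 at 0.22 CPM in E1WT 2, Tra2b at 123 CPM in E1WT 3, and Cd109 at 4.05 CPM, Btla at 219 CPM, Tpi1 at 48.2 CPM and Gp5 at 0.737 CPM in E1WT 4.

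The 8 libraries can be split into 4 and 4 in 35 ways. The split by title gave 3108 called genes and the highest of the others gave 0, so 1 split reached that number. That is the smallest share these splits can give, and it met the bound set beforehand. Every other split mixes the titles, so the difference between titles adds to its spread. The title split thus stood apart in called genes. A chance difference between the sources of the libraries is not excluded by this, since separate animals are not stated. For gene lists the title split gave 9, the highest other 10, and 4 splits gave as many, so chance is not excluded for their number. For marker lists the title split gave 5, the highest other 5, and 2 splits gave as many, so chance is not excluded there either. The highest numbers came from splits that keep 3 libraries of a title together (10 and 5), while the 18 splits with 2 of each title on each side gave at most 3 and 1.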

How the results depend on the processing

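Removing the exon-length trend, leaving out E1KO 1 and E1WT 4 together, autosomal genes only and the fold threshold were added after the data were seen. Pcbp1 kept its direction and call under each alternative that groups by title, at -2.56 to -2.45, and stood at 2.49 with groups from the genotype field, which turns the sign by construction. Called genes numbered 1526 to 1862 higher and 1393 to 1888 lower over the other alternatives grouped by title, leaving aside the block and the fold threshold, and 1194 to 1659 higher and 1010 to 1566 lower when 1 library was left out; a test against a 1.5-fold change left 223 higher and 114 lower, as it asks for larger changes. DESeq2 called 1836 and 1888, of which 1620 and 1483 were among the calls above. Gene lists past the threshold numbered 4 with an estimated correlation, 7 to 13 under the other alternatives and 8 to 10 with 1 library left out; marker lists numbered 4 or 5 throughout. The odds ratio for genes near Pcbp1 was 0.52 with the replicate block (exact p = 0.049), and 0.485 to 0.819 with 1 library left out; the cause was not tested. The replicate numbers did not pair the libraries (correlations of deviations 0.01, -0.05, -0.03 and -0.10, 0 of 8 best with their own number), and the block gave 1151 higher, 1005 lower and 7 gene lists. Of 135 named genes past the threshold 120 kept direction and call under each alternative grouped by title that tested them, the fold threshold aside, and 0 reversed. In the simulation, 20% of genes with the smallest fold were recovered. It gave 133 calls against 3108 in the real data, so that share need not carry over.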

Other observations

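The genes here were picked after their values were seen. Pmel and Dgka converge on chromosome 10: Pmel runs from 128704195 to 128720238 on the plus strand and Dgka from 128720134 to 128744855 on the minus strand. Pmel, known as a melanosome gene, stood at 6.20 ± 1.26 CPM in E1KO-titled and 26.7 ± 1.81 CPM in E1WT-titled libraries (SD, n = 4 each). Dgka stood at 527 ± 19.9 and 1365 ± 21.4 CPM. Reads of the overlap cannot be assigned, since strand use is not given.

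Some genes encoding stress and death regulators differed in opposite ways. Bbc3 went from 24.7 ± 4.58 to 53.5 ± 3.13 CPM and Phlda3 from 1.47 ± 0.36 to 5.90 ± 1.35 CPM, while Fasl went from 10.3 ± 0.59 to 4.55 ± 0.41 CPM. Asns, Phgdh and Sesn2, genes of the amino acid and integrated stress response, had log2 folds of 1.89 ± 0.11, 0.39 ± 0.06 and 0.93 ± 0.15, and Edem1 one of -0.35 ± 0.05.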
